A study of Danio rerio with 6 samples.

How the data were processed

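Whole zebrafish embryos were collected at 32 hpf as 3 wild-type and 3 supt16h-/- samples of 40 embryos each, per the labels. RNA was extracted with Trizol and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA. The labels do not say what the supt16h mutation is, nor that libraries with the same number came from the same clutch. They do not describe how the embryos of a sample were raised or selected. P-values of single genes therefore measure the spread between these 3 samples of each genotype.

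FastQC, TopHat and Cufflinks and the genome build GRCz11 are named in the submitters' processing notes. Their versions, the annotation and the read counts were not given in the sources used here. The authors deposited 1 table with a value per gene and library in FPKM, fragments scaled by transcript length and by the mapped fragments of the library, per the file headers. The table also holds the authors' p-value and q-value for wild type against mutant and their log2 fold change, per the file headers. The authors' log2 fold change lay within 0.1 of the log2 ratio of the group means of FPKM for 99.5% of 19348 genes with a value in both. Of 32189 genes in the deposited table, 38 carried no FPKM; 37 of these were mitochondrial, so no mitochondrially encoded gene was measured. FPKM are relative amounts within a library: when some genes take a smaller share, the others take a larger one.

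The depth of each library is unknown. The deposited FPKM were searched for the step of a single read among genes of low value. Only wild-type replicate 1 was set against each other library. At most 11.5% of the 42 to 79 such genes in any of these pairs shared a ratio to within a narrow band. This search therefore recovered neither read counts nor relative depth, and no counting interval is given. The summed FPKM, the number of genes at 1 FPKM or more and the share of the 10 most abundant genes describe each library in place of depth. An FPKM of exactly 0 can be a failed estimate: 7 genes stood at 0 in 1 library and at 5 FPKM or more in the other 5.

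The main test was limma-trend (limma 3.58.1 in R 4.3.3, empirical Bayes with trend and robust options, statmod 1.5.0) on log2(FPKM + 1). It took 17911 genes with at least 1 FPKM in 3 or more libraries and all 6 libraries, with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes from the fit are on the log2(FPKM + 1) scale and understate the change of genes of low value; folds named as ratios of means are ratios of mean FPKM. Gene names were those of the table; 26350 of its gene IDs were also found in a reference table of names. Of several genes that carried 1 symbol (643 symbols), the one with the highest mean FPKM was used. Genes that share sequence with near-identical copies, such as the her4 genes, globins, histones and 5S rRNA, have uncertain single values, since how reads were divided among copies is not given in the sources used here.

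Before the data were examined, 47 gene lists of pathways, processes and cell types of the embryo were fixed, with 1852 entries, of which 1795 were found in the table (38 of them through the reference names). Each list was tested against all other tested genes with camera at its preset correlation of 0.01, adjusted over the 47 lists. With this preset the p-values of camera rest mainly on the spread across genes and not between samples. Camera with a correlation estimated from the residuals, and fry, were run beside it. Fry asks whether the members of a list move on balance in 1 direction and does not compare the list with other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. A list is named by its theme only as a set of genes. The rule for named genes was also fixed beforehand. It took supt16h, ssrp1a, ssrp1b, mdm2, cdkn1a, ccng1, phc1, notch1a, notch1b, notch2, notch3, dlc, dld, runx1, myb, gata2b, kdrl and efnb2a in any case; 1 other gene so named and 1 of the lists are not reported here. It added the 10 largest rises and 10 largest falls past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups. For each list it took up to 4 members past the threshold with the largest absolute change, or, where fewer than 2 passed, the 2 most highly expressed. For results that changed with the processing, up to 3 genes with the smallest adjusted p could be added. Other genes named here were chosen after their values were seen.

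The fit was tested on simulated data for mutant against wild type with the same 17911 genes, 200 of them changed. It recovered 40% of genes changed by 0.5 on the log2 scale, 76% of those changed by 1, 98% of those changed by 2 and 98% of those changed by 4, with 8 false calls among 164. A shift of -0.5 given to the 45 tested members of the Notch list was called at a camera adjusted p of 6.0e-65, with 2 of the 47 lists called besides it. Lists that share Notch members were not set aside. The simulated noise was drawn separately for each gene, while the estimated correlation of the Notch list in the data was 0.164. The data also held more changed genes, 5364, so these rates and p-values need not hold there.

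Libraries with the same number deviated together from their group means: the correlations across genes were 0.37 for number 1, 0.16 for number 2 and 0.26 for number 3, while pairs with different numbers lay between -0.27 and 0.06. All 3 exceeded 0.1, so the numbers may pair the libraries, on the evidence of the data and not of the labels. The deviations of 3 libraries sum to 0 in each group, so such a match could also arise by chance. The main test left the numbers out. A fit with the number as a block was run as an alternative, as planned beforehand. Other alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter at 5 FPKM, median-of-ratios scaling, a 2-fold minimum, an adjusted p under 0.01, the authors' q-value, and leaving out each library in turn on the same genes. Leaving out number 1 of both groups, leaving supt16h out of the list of histone chaperones, and a 2-fold minimum on the ratio of mean FPKM for genes near supt16h, were added after the data were seen. Of counts of list members, those of 2 genes or fewer are not followed through the alternatives unless stated. supt16h and ssrp1a were also compared by an exact two-sided permutation test, which cannot give a p below 0.1 with 3 libraries against 3. Gene neighbours were taken from a RefSeq table of the assembly GRCz12tu, a different build, so no coordinates are given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used to read the table and draw the plots.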

Results

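Gene expression was measured by RNA sequencing of whole zebrafish embryos at 32 hpf (hours post fertilization), as 3 wild-type and 3 supt16h-/- libraries of 40 embryos each. supt16h encodes Spt16, a subunit of the histone chaperone FACT, which takes nucleosomes apart and puts them back during transcription and replication. The libraries held 17554 to 17806 genes at 1 FPKM or more. Summed FPKM was 655538 to 674830 in wild type and 697194 to 713783 in mutants, and the 10 most abundant genes took 7.17% to 7.4% and 7.64% to 8.21% of it. Log2 values correlated at 0.981 to 0.989 within wild type, 0.979 to 0.987 within mutants and 0.962 to 0.971 between genotypes. The first principal component, with 53.1% of the variance, separated the genotypes, and the second, with 21.1%, set the libraries numbered 1 of both genotypes apart from the others. All errors of FPKM are SD with n = 3 libraries per genotype.

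The comparison asked which transcripts differ when supt16h is lost. supt16h itself (ENSDARG00000079949) was 41.21, 35.31 and 36.02 FPKM in the wild-type libraries and 7.54, 2.80 and 4.98 in the mutants. The means were 37.5 ± 3.22 and 5.11 ± 2.37, a 7.35-fold difference, and the gene fell by 2.73 on the log2 scale (SE 0.281, limma adjusted p = 0.00112). ssrp1a (ENSDARG00000037397), which encodes the FACT partner subunit, fell from 60.0 ± 0.344 to 49.3 ± 3.45 FPKM (log2 fold change -0.28, SE 0.064, limma adjusted p = 0.0123). Its paralog ssrp1b was at 2.51 ± 0.373 and 3.36 ± 0.231 FPKM and did not pass (log2 fold change 0.32, SE 0.120, limma adjusted p = 0.0828). The exact two-sided permutation test gave p = 0.1 for supt16h and for ssrp1a, the smallest it allows with 3 libraries against 3.

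Of 17911 genes tested, 5364 changed at a limma adjusted p under 0.05 (29.9%), 2669 higher and 2695 lower in mutants. Falls were larger: of 371 genes that changed 2-fold or more, 312 were lower and 59 higher. The cell cycle inhibitor cdkn1a rose from 1.79 ± 0.893 to 21.2 ± 2.80 FPKM, the ubiquitin-like interferon-response gene isg15 from 0.133 ± 0.197 to 10.4 ± 1.48, and the growth arrest gene gadd45aa from 3.07 ± 0.335 to 18.1 ± 0.478. The erythrocyte anion exchanger slc4a1a fell from 107 ± 10.5 to 10.9 ± 5.57 FPKM and atoh7, which specifies retinal ganglion cells, from 16.7 ± 1.65 to 1.69 ± 0.931. The other large rises were fosab, phlda3, nupr1a (so named only in the reference table), zgc:172079, and the uncharacterized si:ch73-65n21.1 and si:ch73-65n21.2, which went from 0.443 ± 0.0252 to 14.4 ± 1.23 and from 0.603 ± 0.422 to 17.8 ± 2.35 FPKM. A gene named 5S_rRNA (ENSDARG00000104133), 1 of 758 with that name, was listed at 0 in every wild-type library and at 64.99, 50.38 and 24.58 FPKM in the mutants. Reads of such copies cannot be assigned with certainty, and the libraries, made from polyadenylated RNA, were not made to measure ribosomal RNA. The authors' deposited table did not select this gene (q-value 0.323). The other large falls, besides supt16h, were of uncharacterized genes, among them si:ch73-21g5.7, from 248 ± 12.9 to 34.3 ± 13.5 FPKM, and si:ch211-132d3.4, from 49.7 ± 1.92 to 7.41 ± 3.73. The groups did not overlap for 8080 genes (45.1%, against 10% by chance). The authors' deposited table selected 4839 genes, 2051 higher and 2788 lower. Of the genes that changed here, 3982 were selected in the authors' deposited table, all 3982 with the same sign. Both comparisons used the same 6 libraries, so the shared sign adds no support. A further 1382 genes changed here only, and 646 tested genes were selected by the authors only. Without wild-type replicate 2, the genes higher in mutants numbered 1677.

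**Figure D1:**
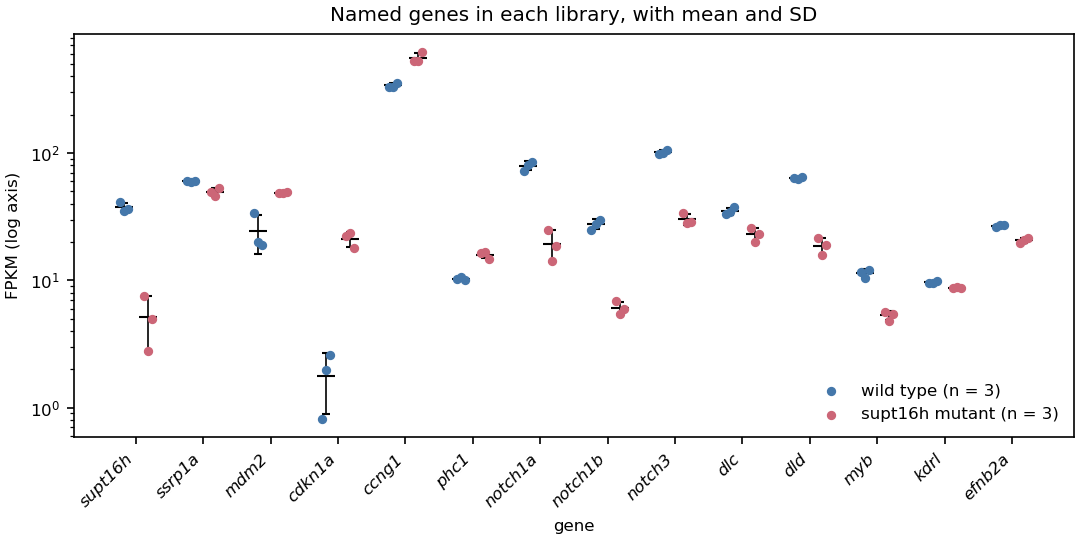
FPKM on a log axis of 14 genes named beforehand, for 3 wild-type libraries (blue) and 3 supt16h mutant libraries (red); points are libraries and bars the mean and SD. supt16h was at 2.80 to 7.54 FPKM in mutants against 35.31 to 41.21 in wild type, mdm2 and cdkn1a were higher, and notch1a, notch1b, notch3 and dld lower.

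Several single genes and the list of intrinsic apoptosis were higher in mutants. Besides cdkn1a and gadd45aa, with log2 fold changes of 3.04 and 2.24, the ubiquitin ligase gene mdm2 rose from 24.2 ± 8.13 to 48.9 ± 0.682 FPKM, with wild-type replicate 1 at 33.61. The cyclin gene ccng1 rose from 340.7 ± 15.15 to 560.5 ± 52.62 FPKM. Of 23 tested genes of intrinsic apoptosis 11 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0202; adjusted p = 0.153 with an estimated correlation). The genes bbc3, birc5a and baxa rose by 1.92, 1.19 and 0.94 on the log2 scale; birc5a encodes survivin, an inhibitor of apoptosis that also acts in mitosis. The apoptosis genes that rose numbered 7 without wild-type replicate 1, wild-type replicate 3 or mutant replicate 2.

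The lists of innate immune, immediate early, and heat shock and oxidative stress genes passed upward. Of 24 tested innate immune and interferon genes 9 rose and none fell (11 and 0 adjusted over the list alone), with isg15, the AP-1 gene fosl1a, the interferon-signalling factor irf9 and the cytokine-signalling inhibitor socs3b at log2 fold changes of 3.33, 1.09, 1.01 and 0.93 (camera adjusted p = 5.8e-04; adjusted p = 0.108 with an estimated correlation). Of 26 immediate early genes 12 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.0175; adjusted p = 0.449 with an estimated correlation). fosab rose from 2.53 ± 1.54 to 14.7 ± 5.75 FPKM, and junba and junbb by 1.48 and 1.26 on the log2 scale. Of 43 heat shock and oxidative stress genes 18 rose and 2 fell (18 and 2 adjusted over the list alone; camera adjusted p = 0.00241; adjusted p = 0.226 with an estimated correlation), including sod2, gpx1b, nfe2l2b and hspb8 at 0.99, 0.96, 0.66 and 0.56. Of 52 genes of the integrated stress and unfolded protein response 10 rose and 6 fell (11 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.443). Among them nupr1a rose by 1.83 on the log2 scale and the stress factors trib3 and atf4b fell (-0.73 and -0.65). Neither junba nor junbb passed when any 1 wild-type library was left out (limma adjusted p of 0.0731 to 0.112), nor junbb without mutant replicate 2 (limma adjusted p = 0.0991). The immediate early list did not pass without mutant replicate 1 (camera adjusted p = 0.0683). Without wild-type replicate 2 the genes that rose numbered 5 of the immediate early list, 11 of the heat shock list and 5 of the integrated stress list. They numbered 5, 10 and 5 without wild-type replicate 3, 6 and 11 of the first 2 lists without mutant replicate 2, and 5 of the immune list without wild-type replicate 1 against 14 with the replicate number as a block.

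Notch pathway genes were lower in mutants. Of the receptors, notch1a fell from 79.6 ± 6.67 to 19.3 ± 5.49 FPKM, notch1b from 27.61 ± 2.502 to 6.09 ± 0.695 and notch3 from 102 ± 4.34 to 30.2 ± 3.21, while notch2 was at 11.9 ± 0.839 and 10.4 ± 0.606 and did not pass (log2 fold change -0.18, SE 0.084, limma adjusted p = 0.141). Among the ligand genes, dla and dld fell, with log2 fold changes of -2.02 and -1.73 (SE 0.124 and 0.102), as did dlc (-0.59, SE 0.099, limma adjusted p = 0.00325). The Notch-responsive her4.2 and her4.4, near-identical copies whose single values are uncertain, fell from 39.9 ± 3.46 to 8.25 ± 1.41 and from 38.3 ± 5.63 to 8.82 ± 4.24 FPKM. Of 45 tested members 34 fell and none rose (36 and 0 adjusted over the list alone), with a median log2 fold change of -0.71 (camera adjusted p = 1.0e-17; adjusted p = 0.108 with an estimated correlation).

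Neural progenitor markers fell with them. Of the 45 Notch members 34 stood on none of the 4 lists of neural progenitor, early neuronal, glial and eye genes, and 23 of these 34 fell, with a median of -0.65. Of 39 tested neural progenitor genes 37 fell and 1 rose (37 and 1 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 3.8e-21; adjusted p = 0.138 with an estimated correlation). sox9b, a factor of glial and neural crest precursors, fell from 27.6 ± 0.355 to 9.37 ± 1.54 FPKM. Of 49 proneural and early neuronal genes 39 fell and none rose (40 and 0 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 3.8e-21; adjusted p = 0.108 with an estimated correlation). Besides atoh7 and dla, the hindbrain proneural gene atoh1b fell from 16.4 ± 1.01 to 3.76 ± 0.350 FPKM and scrt1b from 4.43 ± 1.15 to 0.617 ± 0.204. Of 38 mature neuron genes 4 rose and none fell (0 and 0 adjusted over the list alone), with a median of 0.06, and the list did not pass (camera adjusted p = 0.224). The neurofilament gene nefma went from 4.93 ± 0.385 to 6.70 ± 0.446 FPKM (limma adjusted p = 0.0195), a call lost without wild-type replicate 2, wild-type replicate 3, mutant replicate 2 or mutant replicate 3 (limma adjusted p = 0.0763, 0.0601, 0.0528 and 0.0662). The mature neuron genes that rose numbered 2 without wild-type replicate 1, and 1 without wild-type replicate 3, mutant replicate 2 or replicate 1 of both groups. The median of this list ranged from 0.021 without mutant replicate 3 to 0.1 without mutant replicate 1.

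The glial and eye lists passed downward too. Of 16 glia and myelin genes 8 fell and 3 rose (9 and 3 adjusted over the list alone; median -0.35, camera adjusted p = 0.00362; adjusted p = 0.226 with an estimated correlation). plp1a, a myelin proteolipid gene, fell from 99.0 ± 6.53 to 19.9 ± 4.39 FPKM, and the radial glial genes gfap and fabp7a from 98.0 ± 1.45 to 37.6 ± 4.55 and from 485 ± 23.5 to 213 ± 24.8. Of 42 genes of the retina and lens 15 fell and none rose (15 and 0 adjusted over the list alone; median -0.31, camera adjusted p = 3.3e-06; adjusted p = 0.258 with an estimated correlation), among them atoh7, rx2, pax6a and vsx1 (log2 fold changes -2.77, -1.38, -1.13 and -1.03). Without mutant replicate 2 the eye genes that fell numbered 9 and the glial genes that rose 1.

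**Figure D2:**
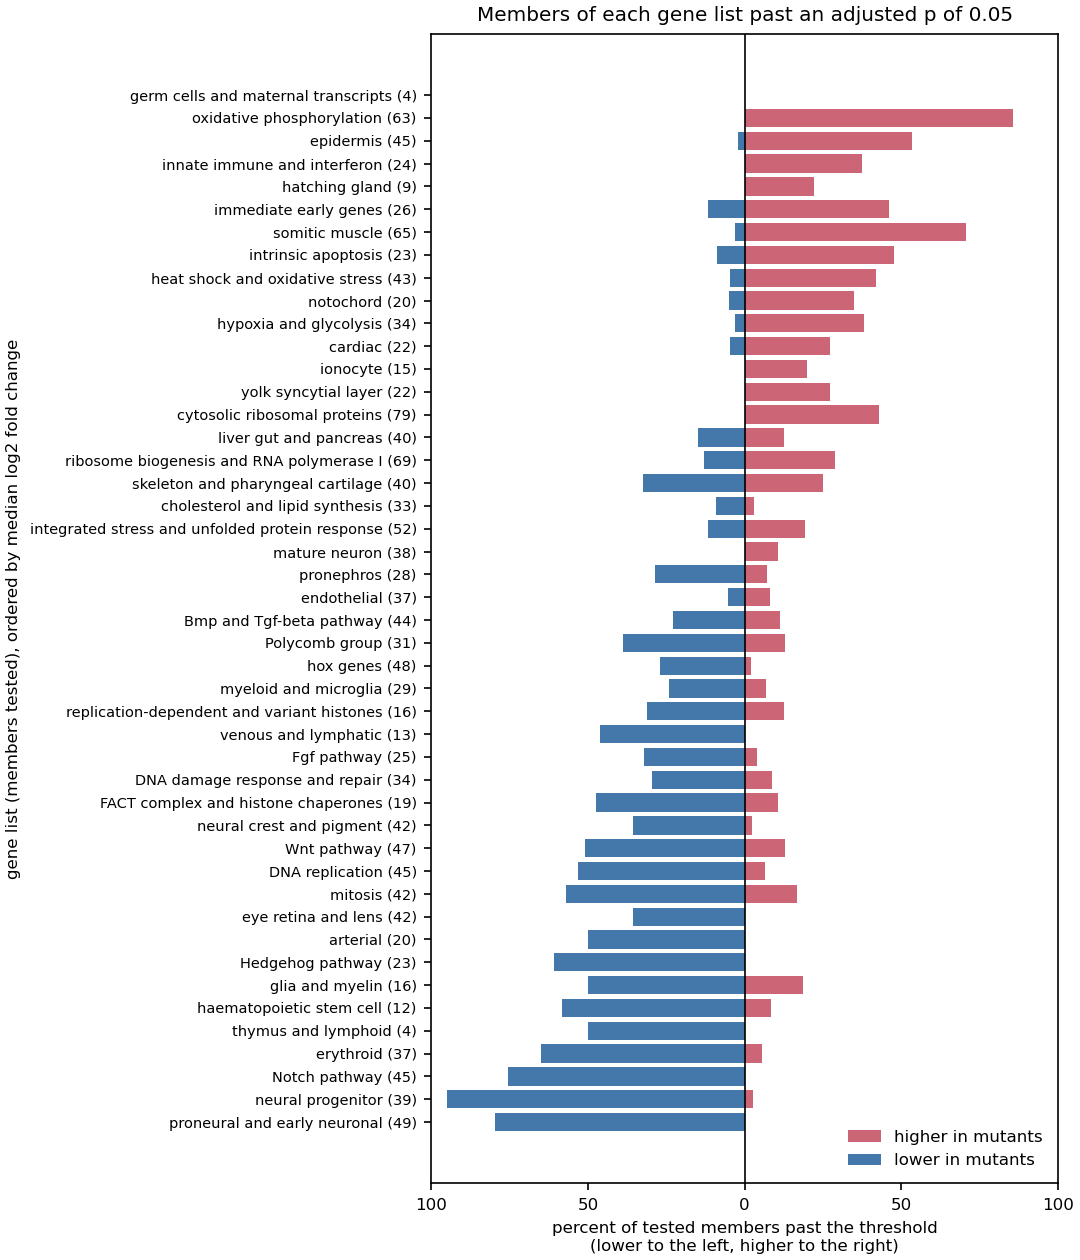
Percent of the tested members of each of 46 gene lists that were higher (red, to the right) or lower (blue, to the left) in mutants at a limma adjusted p under 0.05, with the number of members tested in brackets and lists ordered by median log2 fold change. Neural progenitor, early neuronal, Notch and erythroid genes stand at the lower end, and oxidative phosphorylation and epidermis genes near the upper end.

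Genes of DNA replication and mitosis were lower. Of 45 replication genes 24 fell and 3 rose (27 and 3 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 5.0e-08; adjusted p = 0.173 with an estimated correlation). The replicative helicase gene mcm2 fell from 99.6 ± 4.24 to 46.4 ± 5.19 FPKM, the ribonucleotide reductase gene rrm1 from 163 ± 1.25 to 80.8 ± 3.65, and mcm4 from 81.6 ± 0.989 to 42.0 ± 4.02. Of 42 mitosis genes 24 fell and 7 rose (26 and 9 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 9.4e-06; adjusted p = 0.226 with an estimated correlation). top2a, a topoisomerase gene, fell from 98.7 ± 0.350 to 39.5 ± 2.44 FPKM and the kinetochore gene cenpf from 22.1 ± 0.871 to 8.82 ± 0.410, while birc5a rose. Of 34 DNA damage response and repair genes 10 fell and 3 rose (10 and 3 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.00891; adjusted p = 0.258 with an estimated correlation). The histone variant gene h2afx, the mismatch repair gene msh6 and the ligase gene lig1 fell, with log2 fold changes of -0.89, -0.58 and -0.51. The replication genes that rose numbered 1 without wild-type replicate 2 or wild-type replicate 3.

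Chromatin genes moved in both directions. Of 19 genes of FACT and other histone chaperones, supt16h among them, 9 fell and 2 rose (9 and 3 adjusted over the list alone; median -0.18, camera adjusted p = 0.0277; adjusted p = 0.383 with an estimated correlation). Without supt16h, the mutated gene, the list did not pass, a test chosen after the result was seen: of 18 genes 8 fell and 2 rose (median -0.15, camera adjusted p = 0.0666; adjusted p = 0.44 with an estimated correlation). nap1l1, chaf1a and hira, which encode chaperones of nucleosome assembly, fell, with log2 fold changes of -0.55, -0.55 and -0.51. Of 31 Polycomb group genes, whose products keep genes silent, 12 fell and 4 rose (13 and 4 adjusted over the list alone; median -0.06, camera adjusted p = 0.0487; adjusted p = 0.307 with an estimated correlation). phc1 rose from 10.3 ± 0.265 to 15.9 ± 1.07 FPKM (log2 fold change 0.58, SE 0.076, limma adjusted p = 0.00116) and cbx7a by 0.94. In contrast cbx6b, scml2 and jarid2b fell (-0.86, -0.74 and -0.63). Of 16 histone genes, whose copies share reads, 5 fell and 2 rose (5 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.192). Polyadenylated RNA was selected, so the levels of histone transcripts without a poly(A) tail were not measured. The linker histone gene histh1l fell by 0.63 and h2afva, a variant histone gene, rose by 0.30. The chaperone list did not pass without wild-type replicate 1 or replicate 1 of both groups (camera adjusted p = 0.0516 and 0.0535), and the Polycomb list without wild-type replicate 3, mutant replicate 1 or mutant replicate 2 (0.0979, 0.0683 and 0.058). The Polycomb median was -0.024 without wild-type replicate 3, -0.026 without mutant replicate 1, -0.112 without mutant replicate 3 and -0.097 with median-of-ratios scaling. Polycomb genes that rose numbered 2 without wild-type replicate 2, mutant replicate 2 or mutant replicate 3, and histone genes that fell 3 without wild-type replicate 1, wild-type replicate 2 or mutant replicate 2.

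Erythroid genes fell by unequal amounts. Of 37 tested members 24 fell and 2 rose (25 and 4 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 4.4e-08; adjusted p = 0.108 with an estimated correlation). slc4a1a, the erythrocyte cytoskeleton gene epb41b, the carbonic anhydrase gene cahz and the haem synthesis gene alas2 fell, with log2 fold changes of -3.29, -2.13, -1.86 and -1.77 (SE 0.369, 0.157, 0.194 and 0.122). Of the globin genes, chosen after their values were seen and uncertain as near-identical copies, hbae3 fell from 4432 ± 399 to 2151 ± 360 FPKM and hbbe1.1 from 2176 ± 417 to 1224 ± 147, while hbz rose from 9.31 ± 0.747 to 18.3 ± 2.49. With the replicate number as a block 5 members rose.

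**Figure D3:**
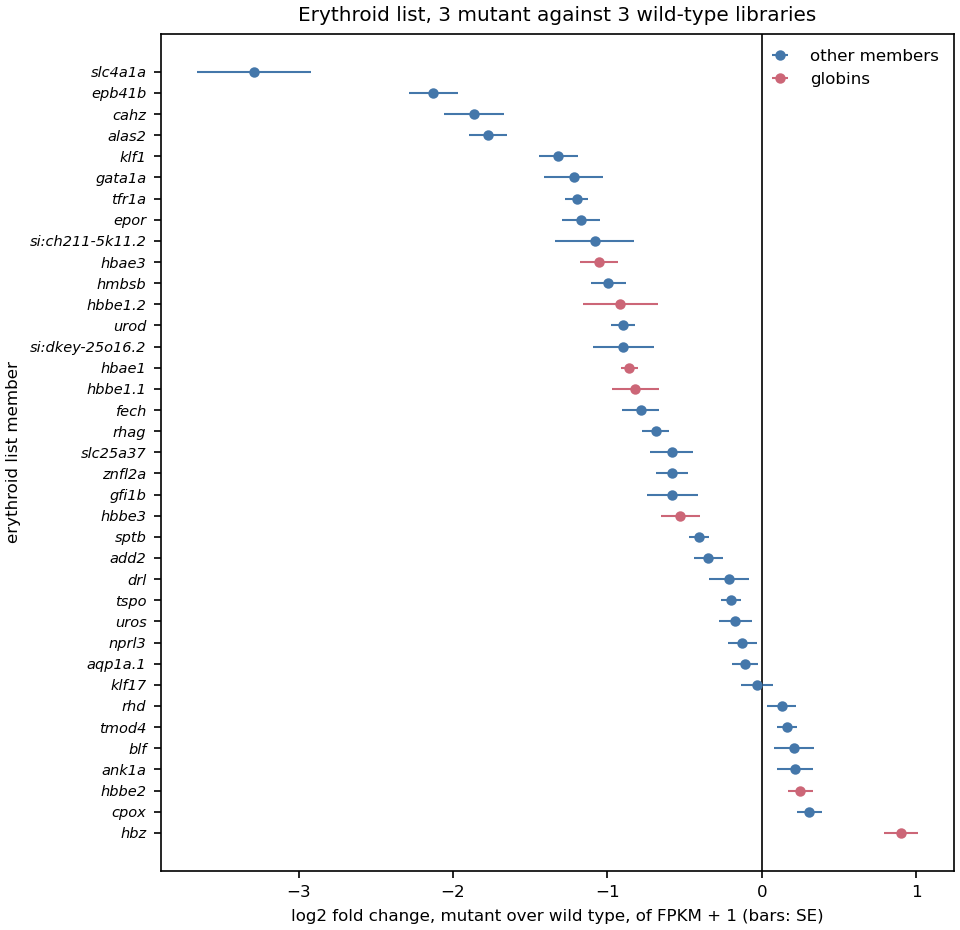
Log2 fold change of FPKM + 1, mutant over wild type, with its SE, for 37 members of the erythroid list (globins in red, other members in blue; 3 libraries against 3). slc4a1a lies at -3.29, hbae3 at -1.05 and hbz at 0.90.

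The list of haematopoietic stem cell genes passed downward. The libraries are of whole embryos, so the cells in which its members fell are not known. Of 12 haematopoietic stem cell genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.00449; adjusted p = 0.138 with an estimated correlation). myb, needed for definitive blood cells, fell from 11.4 ± 0.910 to 5.31 ± 0.428 FPKM (log2 fold change -0.97, SE 0.095, limma adjusted p = 2.9e-04), as did meis1b, gata2a and tal1 (-0.88, -0.79 and -0.64). runx1, which directs their emergence, was at 1.40 ± 0.367 and 0.32 ± 0.0954 FPKM and gata2b at 0.3 ± 0.07 and 0.28 ± 0.03; both lay under the filter and were not tested, and in the authors' deposited table their q-values were 0.0824 and 1. Of 29 myeloid and microglia genes 7 fell and 2 rose (7 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.188). Among its members the neutrophil genes npsn, mpx and lyz fell, lyz from 141.6 ± 10.01 to 69.4 ± 2.37 FPKM. Of 4 tested thymus and lymphoid genes 2 fell and none rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.0407; adjusted p = 0.226 with an estimated correlation): bcl11ba from 4.28 ± 0.444 to 2.60 ± 0.360 FPKM and gata3 from 14.8 ± 0.365 to 10.1 ± 0.200. The lymphoid list did not pass with median-of-ratios scaling (camera adjusted p = 0.0508) or without wild-type replicate 3, mutant replicate 2 or mutant replicate 3 (0.0914, 0.0623 and 0.052). The members that fell numbered 4 of the stem cell list without wild-type replicate 2 or mutant replicate 2 and 4 of the myeloid list without either of these or wild-type replicate 3, and 6 myeloid genes rose with the replicate number as a block.

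Of 3 vessel lists, that of arterial genes passed at the preset correlation and not with an estimated one (camera adjusted p = 4.7e-06 and 0.0954), and no test compared the lists with each other. kdrl, the endothelial Vegf receptor gene, was at 9.64 ± 0.224 and 8.76 ± 0.0839 FPKM and did not pass (log2 fold change -0.12, SE 0.072, limma adjusted p = 0.237). Of 37 endothelial genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.843). Without wild-type replicate 3 or replicate 1 of both groups the median was -0.037 and -0.007 and the direction of the test downward, as it was without mutant replicate 1, and without replicate 1 of both groups 1 gene rose. The median was 0.054 without wild-type replicate 2 and 0.01 with median-of-ratios scaling. tal1 and fli1a, which act in blood and vessel precursors, fell (log2 fold changes -0.64 and -0.60), and the receptor genes tek and aplnrb rose by 0.51 and 0.45. Of 20 arterial genes 10 fell and none rose (11 and 0 adjusted over the list alone), with a median of -0.33. They included notch1b, notch3 and hey2 (-1.09), all also on the Notch list. The 2 lists share dlc and dll4 as well, and the arterial list was not tested without the shared genes. efnb2a, which encodes an arterial ephrin, fell from 26.8 ± 0.697 to 20.7 ± 0.921 FPKM (log2 fold change -0.36, SE 0.064, limma adjusted p = 0.00426). Of 13 venous and lymphatic genes 6 fell and none rose (6 and 1 adjusted over the list alone), among them ephb4a, from 16.9 ± 1.41 to 11.8 ± 0.266 FPKM, and prox1a, from 9.93 ± 0.270 to 7.11 ± 0.795, and the list did not pass (camera adjusted p = 0.122).

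Somitic muscle and epidermis genes were modestly higher. Of 65 somitic muscle genes 46 rose and 2 fell (51 and 2 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 7.3e-12; adjusted p = 0.165 with an estimated correlation). The acetylcholine receptor subunit gene chrng rose from 3.45 ± 0.827 to 8.38 ± 1.14 FPKM, the calcium-binding parvalbumin gene pvalb3 from 84.3 ± 3.74 to 127 ± 10.3 and the troponin gene tnni2b.1 from 336 ± 16.7 to 475 ± 31.5. Of 22 cardiac genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), cmlc1, nppa, tnnc1a and myl7 by 0.46 to 0.56 on the log2 scale, and the list did not pass (camera adjusted p = 0.101). Of 45 epidermis genes 24 rose and 1 fell (28 and 1 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 4.4e-08; adjusted p = 0.226 with an estimated correlation). perp, a desmosome component gene, rose from 82.2 ± 1.53 to 117 ± 3.87 FPKM and the claudin gene cldni from 124 ± 6.61 to 170 ± 3.30. Of 20 notochord genes 7 rose and 1 fell (9 and 2 adjusted over the list alone), the caveolin gene cav1 rising by 0.56 and the collagen gene col9a1a falling by 0.68; the list did not pass (camera adjusted p = 0.073) except without mutant replicate 3 (0.0397), and 4 members rose without wild-type replicate 2 or wild-type replicate 3.

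Of the signalling lists, those of the Wnt, Hedgehog and Fgf pathways passed downward. Of 47 Wnt pathway genes 24 fell and 6 rose (25 and 6 adjusted over the list alone; median -0.29, camera adjusted p = 2.5e-05; adjusted p = 0.0954 with an estimated correlation), with the transcription factor gene tcf7l2 from 27.76 ± 1.69 to 11.95 ± 0.855 FPKM and the ligand gene wnt1 from 3.897 ± 0.150 to 1.297 ± 0.253. Of 23 Hedgehog pathway genes 14 fell and none rose (15 and 0 adjusted over the list alone; median -0.35, camera adjusted p = 4.4e-08; adjusted p = 0.114 with an estimated correlation), the effector gene gli2b and the co-receptor genes cdon and boc among them (-1.14, -1.07 and -1.03). Of 25 Fgf pathway genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.14, camera adjusted p = 0.00449; adjusted p = 0.114 with an estimated correlation), including the receptor genes fgfr2, fgfr1b, fgfr4 and fgfr3. Of 44 Bmp and Tgf-beta pathway genes 10 fell and 5 rose (11 and 6 adjusted over the list alone), gdf11 from 8.99 ± 0.517 to 3.40 ± 0.725 FPKM and smad7 from 14.9 ± 0.791 to 7.893 ± 1.001, and the list did not pass (camera adjusted p = 0.312). Of 48 hox genes, which pattern the body axis, 13 fell and 1 rose (12 and 1 adjusted over the list alone; median -0.07, camera adjusted p = 0.0265; adjusted p = 0.404 with an estimated correlation), hoxb3a from 40.2 ± 1.21 to 18.9 ± 0.879 FPKM. The hox list did not pass without wild-type replicate 1, mutant replicate 2 or replicate 1 of both groups (camera adjusted p = 0.106, 0.0522 and 0.0765), and its median was -0.107 without wild-type replicate 3. Between 1 and 3 Wnt genes rose when any 1 library was left out, and without wild-type replicate 2 or wild-type replicate 3 the Bmp and Tgf-beta genes that fell numbered 6 and 5. Those that rose numbered 2 without wild-type replicate 2, mutant replicate 2 or mutant replicate 3, and 3 without wild-type replicate 1, wild-type replicate 3 or replicate 1 of both groups or with median-of-ratios scaling.

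The list of neural crest and pigment genes passed downward. Of 42 neural crest and pigment genes 15 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 2.3e-04; adjusted p = 0.14 with an estimated correlation). The iridophore gene pnp4a, the melanosome gene oca2 and the mesenchymal factor twist1a fell (log2 fold changes -0.71, -0.68 and -0.67). Of 40 genes of the skeleton and pharyngeal cartilage 13 fell and 10 rose (13 and 12 adjusted over the list alone). The homeobox genes barx1, dlx1a and dlx2a fell (-1.01, -0.93 and -0.77). This list did not pass (camera adjusted p = 0.675), with a median of 0.10, a mean of -0.09 and a downward direction of the test. The median was 0.055 without mutant replicate 1, 0.032 without replicate 1 of both groups and 0.063 with median-of-ratios scaling. Neural crest genes that fell numbered 9, 8 and 9 without wild-type replicate 2, wild-type replicate 3 and mutant replicate 2, and skeletal genes that rose numbered 5 without wild-type replicate 2.

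In all, 31 of the 47 lists passed with camera at its preset correlation, 12 upward and 19 downward. With an estimated correlation and 4 residual degrees of freedom 0 passed (lowest camera adjusted p 0.0945), 15 were under an unadjusted p of 0.05, and 37 passed with fry. Other splits of the same 6 libraries into 3 against 3 gave 9 to 23 lists past the camera threshold. Each of these splits sets 2 libraries of one genotype and 1 of the other against the reverse and so keeps part of the genotype difference. Their counts therefore do not show how many lists camera would call without such a difference. Of the 31 lists, 21 had their smallest p in the real split, and 10 had a smaller p in another split. These 10 were the lists of histone chaperones, lymphoid, eye, ionocyte, yolk, cytosolic ribosomal protein, heat shock and oxidative stress, innate immune, immediate early and hox genes.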

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

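Leaving out replicate 1 of both groups, and supt16h from its list, were chosen after the result was seen. Of 186 named genes past the threshold, 162 passed in all 6 fits without 1 library, and none changed sign under any setting run. The rule chose many of them for large changes in these same libraries, which favours both results. Of all 5364 genes called, 3656 (without wild-type replicate 2) to 4599 (without mutant replicate 1) were called again. Of 31 gene lists, 25 passed in all 6 of these fits. A 2-fold minimum left 371 genes (59 higher, 312 lower) and an adjusted p under 0.01 left 2941 (1200 and 1741), as stricter thresholds must. With an estimated correlation 0 lists passed camera. Without 1 library, 3726 to 5256 genes changed, 1677 to 2775 higher and 2044 to 2481 lower, 28 to 32 lists passed, and the log2 fold change was -3.01 to -2.43 for supt16h and -0.33 to -0.23 for ssrp1a; the lowest count of higher genes came without wild-type replicate 2, and the cause was not tested. With the replicate number as a block 6763 genes changed (3658 higher, 3105 lower), all 186 named genes past the threshold passed, and 32 lists passed; among lists it changed the call of the hatching gland alone. Median-of-ratios scaling gave 5286 genes (2287 higher, 2999 lower) and 29 lists. Pseudocounts of 0.1 and 5 gave 5326 and 5386 genes, no filter 4724, a filter at 5 FPKM 4986, and leaving out replicate 1 of both groups 5121 and 31 lists (2 lost, 2 gained). The alternatives that need counts were not run, since the values are FPKM, and the unknown depth leaves the counting error of genes of low value unknown.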

Other observations

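The tests of the Notch and erythroid patterns, and the ratio of mean FPKM near supt16h, were chosen after the result was seen, while the tests of other splits and the first count of genes near supt16h were set before. Genes of the respiratory chain were higher in mutants. Summed FPKM was also higher in mutants, and a bias by transcript length could not be tested without the annotation. Of 63 tested oxidative phosphorylation genes, all encoded in the nucleus, 54 rose and none fell (54 and 0 adjusted over the list alone), with a median log2 fold change of 0.34 (camera adjusted p = 6.4e-19; adjusted p = 0.0945 with an estimated correlation). The complex I subunit gene ndufa1 rose from 236.4 ± 16.98 to 373 ± 13.2 FPKM (SD, n = 3) and the complex III gene uqcrq from 272 ± 17.6 to 399.8 ± 9.73. Of 79 cytosolic ribosomal protein genes 34 rose and none fell (42 and 0 adjusted over the list alone; median 0.15, camera adjusted p = 1.1e-08; adjusted p = 0.436 with an estimated correlation), rps28 from 1684 ± 58.7 to 2128 ± 51.4. Those that rose numbered 12 with median-of-ratios scaling and 18, 19 and 20 without wild-type replicate 2, wild-type replicate 3 and mutant replicate 1. Of 69 genes of ribosome biogenesis and RNA polymerase I 20 rose and 9 fell (21 and 10 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.122). The nucleolar genes nop56, dkc1 and ncl fell (-0.69, -0.66 and -0.63) and rsl1d1 rose by 0.64. This list passed without wild-type replicate 1 (camera adjusted p = 0.0345). The members that rose numbered 10 without wild-type replicate 3 and 13 without mutant replicate 3, and those that fell 5 without wild-type replicate 1, wild-type replicate 2 or mutant replicate 2. Of 34 hypoxia and glycolysis genes 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 3.2e-04; adjusted p = 0.108 with an estimated correlation), gapdh from 1069 ± 57.8 to 1436 ± 55.8 FPKM. The genes that rose numbered 8 without wild-type replicate 2 or wild-type replicate 3.

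The lists of liver, gut and pancreas genes and of pronephros genes did not pass. Of the first 40 genes 6 fell and 5 rose (6 and 5 adjusted over the list alone; camera adjusted p = 0.268), with a median of 0.13 and an upward direction of the test. ptf1a, which specifies exocrine pancreas and some neurons, fell from 5.967 ± 1.002 to 1.11 ± 0.165 FPKM and the elastase gene ela2 from 3.07 ± 0.545 to 0.65 ± 0.344. Of 28 pronephros genes 8 fell and 2 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.268), with a mean of -0.12 and a downward direction of the test. The median of 0.06 was -0.022 without wild-type replicate 3, 0.027 without mutant replicate 2 and 0.031 with median-of-ratios scaling. mecom, lhx1a and pax2a fell (-1.48, -0.89 and -0.65). Of 22 yolk syncytial layer genes 6 rose and none fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0214; adjusted p = 0.436 with an estimated correlation), the lipoprotein genes mtp and apobb.1 by 0.42 and 0.36. Of 15 ionocyte genes 3 rose and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.00639; adjusted p = 0.35 with an estimated correlation), ca15a from 21.6 ± 1.26 to 29.8 ± 3.03 FPKM. Of 9 hatching gland genes 2 rose and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.0603), he2 from 1.87 ± 0.191 to 3.61 ± 0.527. Of 33 cholesterol and lipid synthesis genes 3 fell, elovl6 among them (-0.39), and 1 rose (0 and 0 adjusted over the list alone; camera adjusted p = 0.761). Of 4 germ cell and maternal genes none passed over all genes and 2 were higher adjusted over the list alone (camera adjusted p = 0.177), with ddx4 at 1.35 ± 0.340 and 2.32 ± 0.634 FPKM. The yolk list did not pass with median-of-ratios scaling (camera adjusted p = 0.054) or without wild-type replicate 3 or mutant replicate 1 (0.0847 and 0.0683). The hatching gland list passed with the replicate number as a block (camera adjusted p = 0.00615) and without wild-type replicate 1, mutant replicate 2 or replicate 1 of both groups (0.0461, 0.0439 and 0.0215), and the germ cell list without wild-type replicate 1 or replicate 1 of both groups (0.026 and 0.0469). With the block the genes that rose numbered 15 of liver, gut and pancreas, 12 of yolk, 5 of hatching gland and 4 each of pronephros and cholesterol genes. They numbered 3 of liver, gut and pancreas with median-of-ratios scaling, 5 of ionocyte genes and 4 of cholesterol genes without mutant replicate 1. Without replicate 1 of both groups they numbered 8 of liver, gut and pancreas, 11 of yolk and 6 of ionocyte genes. The cholesterol genes that fell numbered 1 without wild-type replicate 2 or wild-type replicate 3.

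The 10 splits of the 6 libraries into 3 against 3 are too few for a share under 0.05, and each split but the real one keeps part of the genotype difference. For genes changed, 1 of the 10 splits, the real one, gave 5364, and the highest other gave 1 by limma (912 genes at an unadjusted p under 0.05). Of the 4 splits that part all 3 pairs of like-numbered libraries, the other 3 gave 0 genes. For gene lists, 1 of the 10 splits, the real one, gave 31, and the highest other, which also parts all 3 pairs, gave 23.

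Notch pathway genes were lower. Reads shared between near-identical her genes were argued against as the whole cause by the 32 members that are not her genes. Their median was -0.65 (95% bootstrap interval -1.02 to -0.39). This interval was used after the values were seen. It took the place of the first bound, more than 3 in 4 of these members lower, which was not met (22 of 32). It resampled genes and not libraries, as did the interval below, so neither holds the spread between samples. A younger stage of the mutants was tested by the somitic muscle genes, of which 46 of 65 rose, with a median of 0.29. This met the bound set against it. FPKM are shares, so fewer neural transcripts would raise the share of muscle genes at any stage, and their rise cannot decide the question. The muscle list did not pass with an estimated correlation (camera adjusted p = 0.165), and the mature neuron median of 0.06 decided nothing. The medians of the glial list and of the mixed neural crest and pigment list, -0.35 and -0.22, would go with a younger stage. The second list also holds the progenitor marker sox9b, so its median does not measure pigment alone. The progenitor, replication and mitosis medians were lower as well (-0.76, -0.29 and -0.29), and none of these medians decides the stage. Of the glial list, gfap and fabp7a are also progenitor markers. Fewer neural progenitor cells cannot be told apart from a fall within cells: progenitor markers on the Notch list had a median lower than the other markers by a difference of -0.73, with a wide interval from -1.36 to 0.53, and the 34 Notch members on none of the 4 neural lists, of which 23 fell with a median of -0.65, were not shown to lie outside progenitors.

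Erythroid genes were lower by unequal amounts. This was seen before the test below was chosen, and the test used the same 6 libraries, so it is not independent evidence. Fewer red blood cells with unchanged content were argued against as the whole cause, because of all 30 members other than globins 4 fell more than the summed globins by a linear model with the variance of each gene, adjusted over the 30 (a moderated variance, tried first, gave p-values judged too small). Another 8 fell less or rose, which expression in other tissues would also give, and the summed FPKM of 8 globin genes went from 10490 ± 1226 to 5926 ± 765.5, a log2 ratio of -0.83 (SE 0.143). Reads shared between globin genes cannot be told apart from true differences between single globins, since this sum would fall with or without sharing. Whether red cells were fewer and also less mature was not tested.

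Of the 50 tested genes nearest to supt16h on its chromosome, 0 changed 2-fold or more by limma and 19 changed by any amount, against medians of 1 and 16 over 14158 windows of 50 genes. A strain variant carried with the mutation was expected to give a count above the 95th percentile, 3, and otherwise one at or below the median, 1. The count of 0 met the latter bound, but by less than its counting spread. By the ratio of mean FPKM, which the added 1 does not damp, 5 of the genes that changed differed 2-fold or more, all under 3 FPKM, against a median of 1 and a 95th percentile of 4. The 2 counts point opposite ways, so a strain variant cannot be told apart from its absence.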
